A study of Mus musculus with 2 samples.

How the data were processed

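Foxa2 HiChIP was measured in liver of wildtype mice, with 1 library from mice given vehicle and 1 from mice given GW4064, collected 4 h after gavage. Per the labels, tissue was ligated with the Arima-HiC+ kit and precipitated with a Foxa2-specific rabbit antiserum. Per the submitters' processing notes, reads were processed with HiC-Pro and Bowtie2 2.2.9 on mm10. The HiC-Pro version, read filters, handling of duplicates and any pooling of animals are not given in the sources used here.

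The deposited matrices give the count of contacts for each pair of 50 kb bins, as raw whole numbers with no normalization, for the upper triangle and the diagonal. The deposited bin tables give the bin number used in the matrices, an index that is of no other unit, and they are identical for both libraries, with 54521 bins. The vehicle library held 22686004 contacts and the GW4064 library 29003442. Chromosomes 1 to 19 and X were used, except for the contact classes, which cover the whole bin table.

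With 1 library per group no test of the treatment and no p-value is possible, and counts compare those libraries and not the conditions. Shares have exact Clopper-Pearson 95% intervals and ratios of counts have exact conditional binomial 95% intervals. These cover counting error only. A library effect and a treatment effect cannot be separated by any interval given.

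Distance decay was summarised as mean contacts per bin pair and as a log-log slope from 100 kb to 10 Mb. Bin coverage is all contacts of a bin. Local contacts are cis contacts with other bins up to 1 Mb away. Ratios were scaled to equal totals of the class. Bins with at least 200 contacts over both libraries were counted when the ratio was at least 1.5-fold and its interval excluded 1, beside a seeded random split of the pooled contacts at the real depths. Bin pairs 100 kb to 2 Mb apart with at least 20 contacts were scaled to the totals at the same distance and counted at 2-fold or more. Enriched pairs had at least 10 contacts and at least 2 times the number expected from distance and from the local contacts of both bins, with the GW4064 library thinned to 74.4% of its contacts. Compartments are the first eigenvector of the correlation of observed over expected contacts at 250 kb, oriented by gene density. Strength is the mean of the within-extreme values divided by the between-extreme value. Insulation used a 500 kb window and a boundary depth of at least 0.2 on the log2 scale. Viewpoints used the distance-matched ratio of contacts within 1 Mb.

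The 20 gene lists hold 516 genes, all of which matched the gene table. They are FXR-induced genes, bile acid synthesis and conjugation, bile acid and organic anion transport, nuclear receptors of liver, Foxa and liver transcription factors, secreted hepatocyte proteins, glucose metabolism, lipid and cholesterol synthesis, fatty acid oxidation and PPARA targets, xenobiotic metabolism, circadian clock, immediate early and stress genes, acute phase and inflammation, Kupffer and leukocyte markers, sinusoidal endothelial markers, stellate cell and fibroblast markers, cholangiocyte markers, neuronal genes, skeletal and cardiac muscle genes, and housekeeping genes. Some genes are on more than 1 list. The plan was to use the bin of each start site. The gene table gives no strand, so a locus is instead every bin that overlaps the gene, which had been planned as an alternative. Genes of a list whose bins overlap form 1 locus. The median log2 ratio of a list is given as a percentile among 10000 random lists of protein-coding loci of the same size, matched on contacts and drawn with replacement. A list is called low in the lowest 2.5% of random lists and high in the highest 2.5%, and a locus is called lower or higher when its interval excludes 0.

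The lists, comparisons, thresholds, most of the other settings tried and the rule for named genes were fixed before the data were examined. The rule names Foxa2, Nr1h4, Nr0b2, Abcb11, Slc51a, Slc51b, Cyp7a1 and Cyp8b1, up to 2 highest and 2 lowest loci per list with at least 200 local contacts, the 5 highest and 5 lowest bins with at least 1000, and the 5 highest and 5 lowest bin pairs with at least 50 contacts and a gene. From these, examples are printed, and 2 loci named by the rule are not reported here. Chosen after the data were seen were the relation with gene density (protein-coding genes in 21 bins around each bin), the matching of lists on gene density and compartment, the scaling to the median locus, the list of genes inside 1 bin, the thinning to contacts at 100 kb to 2 Mb, the correction of compartments for contacts between chromosomes, the equal random parts for compartments, the comparison of FXR-induced loci with other liver loci and its allowance for the choice of the lowest list, the regions on chromosomes 10, 12, 13 and 17, and the mitochondrial contacts.

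Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The methods were tested on simulated data. Of 50 bins planted at each level, the bin rule found 100% at 2-fold and 56% at 1.5-fold, and it called 18 of 48890 unchanged bins. The pair rule found 28% at 2-fold, 68% at 4-fold, 40% at 0.5-fold and 84% at 0.25-fold and called 2745 of 88883 unchanged pairs. Lists shifted by -0.2 were called in 85.5% of 200 draws and lists with no shift in 3%. These lists were drawn from independent simulated values, so both rates leave out lists whose loci lie near each other. The enrichment rule found 81% of pairs raised 3-fold and called 5651 pairs that were not raised.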

Results

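Foxa2 HiChIP was performed on livers of wildtype mice collected 4 h after a single oral dose of vehicle or of GW4064, a synthetic agonist of the bile acid receptor FXR. HiChIP joins proximity ligation with chromatin immunoprecipitation, so that each contact is a ligated pair of DNA ends recovered with an antiserum against Foxa2, the forkhead pioneer factor of liver. Each group held 1 library, so there were no replicates, and every difference reported here compares those 2 libraries and not the conditions. The series asks, as its title states, how chromatin conformation differs when FXR is activated and what part Foxa2 plays. The vehicle library held 22686004 contacts and the GW4064 library 29003442, a depth ratio of 1.28. Contacts were counted between 50 kb bins of the mm10 genome, and 88.0% of the bin pairs listed for vehicle and 85.8% of those listed for GW4064 held 1 contact. Intervals are 95% intervals and cover counting error only.

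The GW4064 library held fewer contacts between chromosomes and more contacts at short range than the vehicle library. Contacts between chromosomes made up 22.5% of the vehicle library (exact Clopper-Pearson interval 22.45% to 22.49%) and 18.5% of the GW4064 library (18.45% to 18.48%). Contacts at 100 kb to 500 kb rose from 9.74% (9.73% to 9.75%) to 11.1% (11.14% to 11.16%), and contacts within a bin from 25.1% to 27.1%. Contacts over 10 Mb apart on one chromosome made up 19.2% and 18.7%. After scaling to equal totals within chromosomes, the ratio of GW4064 to vehicle was 1.10 at 150 kb (interval 1.09 to 1.10), passed 1 near 1150 to 1550 kb (ratio 1.00) and reached 0.918 at 6400 to 9000 kb (0.915 to 0.922). The log-log slope between 100 kb and 10 Mb was -0.987 in vehicle and -1.03 in GW4064.

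**Figure D1:**
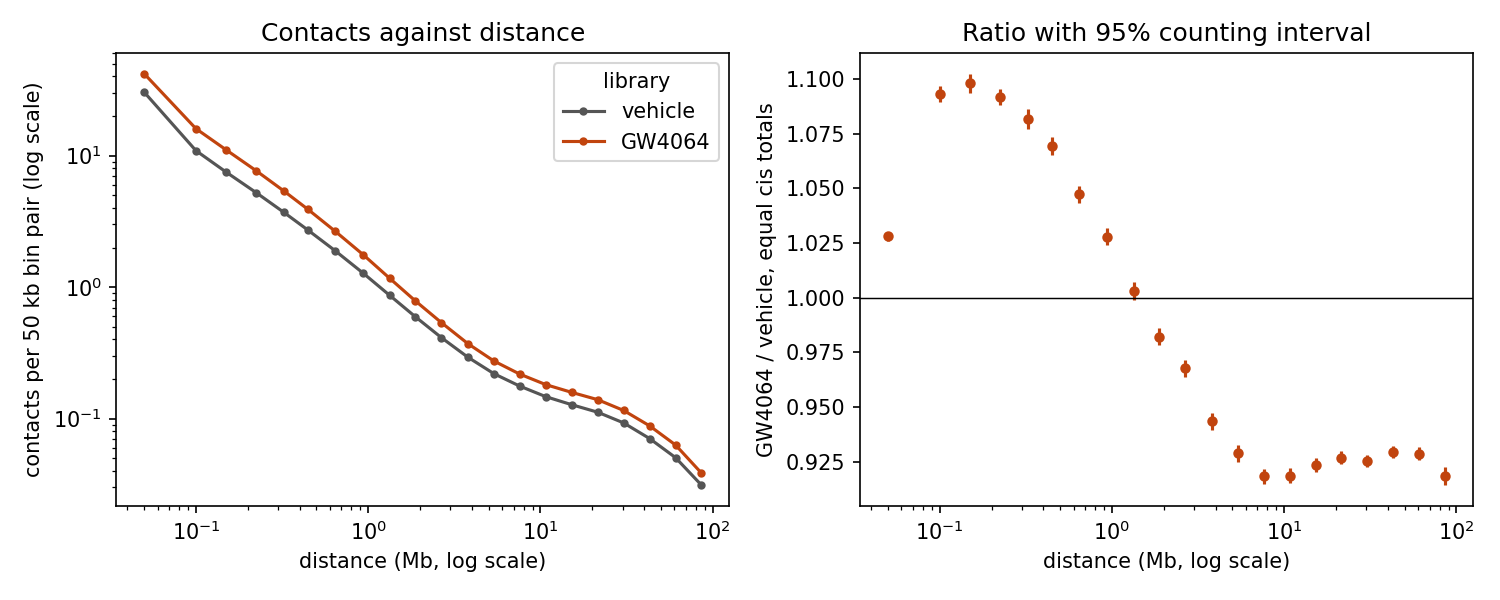
Contacts per 50 kb bin pair against genomic distance in Mb for both libraries, on log axes (left), and the ratio of GW4064 to vehicle after scaling to equal cis totals, with 95% counting intervals (right). The ratio is highest at 150 kb, at 1.10, and 0.918 at 6400 to 9000 kb.

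Gene-rich regions held fewer contacts in the GW4064 library and gene-poor regions held more, a relation looked for after the data were seen. Local contacts, meaning contacts of a bin with other bins up to 1 Mb away, were compared after scaling to equal totals. Bins with no protein-coding gene in the surrounding 21 bins had a median log2 ratio of GW4064 to vehicle of 0.16, and bins with 13 to 76 such genes one of -0.21. The same order appeared in the other contact classes: the gene-rich bins lay lower by a log2 difference of -0.34 for contacts within a bin, -0.36 for contacts over 1 Mb apart and -0.27 for contacts between chromosomes. Across the 49090 bins with at least 200 local contacts, the log2 ratio had a Pearson r of -0.482 and a Spearman rho of -0.505 with gene density, and r was negative on 20 of 20 chromosomes. Bins are not independent replicates, so no p-value is given. Of these bins, 1564 were at least 1.5-fold lower in GW4064 with an interval excluding 1, and 111 were higher. A random split of the pooled contacts at the same depths gave 4 lower and 8 higher. Total contacts per bin gave 631 lower and 29 higher of 50780 bins, and 0 of either in the random split. The gene-rich stretch of chromosome 10 from Arid3a to Nmrk2, 25 bins with 70 protein-coding genes that include Stk11, Gadd45b, Creb3l3 and Eef2, held 2305 vehicle and 1537 GW4064 local contacts, a log2 ratio of -1.09 (interval -1.19 to -1.0). It was singled out after its values were seen.

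**Figure D2:**
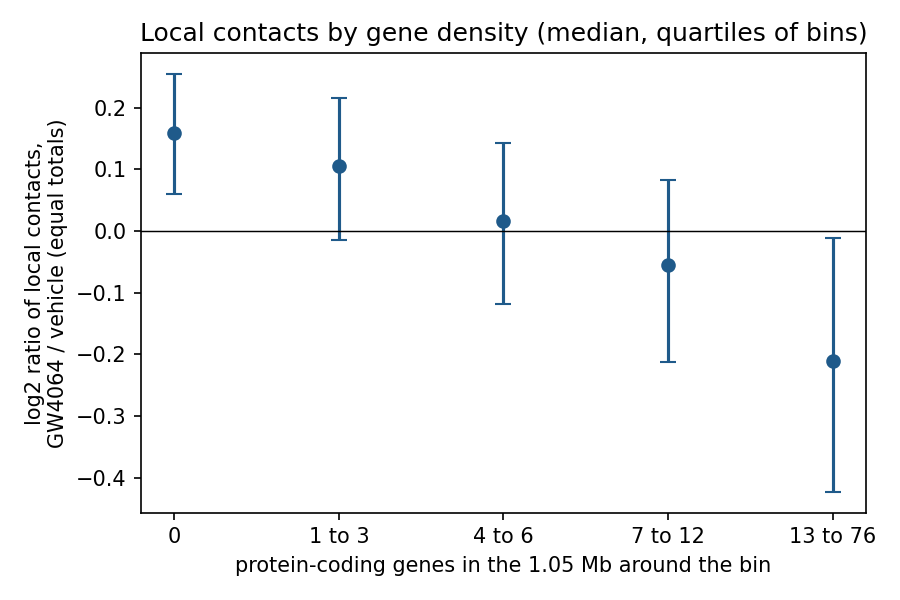
Median log2 ratio of local contacts, GW4064 over vehicle after scaling to equal totals, in 5 groups of bins ordered by the number of protein-coding genes around them. Bars span the quartiles of the bins. The median goes from 0.16 in bins with no gene to -0.21 in bins with 13 to 76 genes.

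Loci of genes that FXR induces in liver held fewer local contacts in the GW4064 library. Of 29 such loci, 21 were lower with an interval below 0, 8 had an interval that includes 0, and 0 were higher. Their median log2 ratio was -0.48, against -0.14 for all protein-coding loci. That median lay at percentile 0.01 of 10000 random lists matched on contacts. The list median was -0.41 with total contacts per bin (percentile 0.02) and -0.48 with contacts within a bin (percentile 0.01). The difference was thus not particular to local contacts, and enrichment of a bin by the immunoprecipitation and its contacts cannot be told apart. Measured against the median protein-coding locus, 17 of the 29 loci lay lower and 0 higher. Scaling to equal total contacts would shift every log2 ratio of local contacts by 0.15, and the list median would then be -0.33. Scarb1, the hepatic receptor for high-density lipoprotein, held 360 vehicle and 254 GW4064 contacts and had a log2 ratio of -1.01 (interval -1.25 to -0.78). Aldh1l1, an enzyme of folate metabolism, had -0.97 (-1.37 to -0.58). The highest members were Vldlr, a lipoprotein receptor, at 0.03 (-0.17 to 0.22), and Akr1b7, an aldo-keto reductase, at 0.01 (-0.27 to 0.29).

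Among the genes chosen in advance as direct readouts of the pathway, 6 of 8 lay lower in the GW4064 library with an interval below 0. The median protein-coding locus itself lay below 0, at -0.14, so this count does not by itself set these genes apart. Nr0b2, the corepressor SHP that FXR induces (chromosome 4, 133553376 to 133556686), held 204 vehicle and 187 GW4064 local contacts, a scaled ratio of 0.644 and a log2 ratio of -0.63 (interval -0.93 to -0.34). Slc51b, a subunit of the basolateral bile acid exporter (chromosome 9, 65412753 to 65422773), had -0.64 (-0.89 to -0.39), and its partner subunit Slc51a (chromosome 16, 32475578 to 32487879) had -0.24 with an interval of -0.49 to 0.02. Abcb11, the bile salt export pump (chromosome 2, 69238282 to 69342616), held 662 and 774 contacts and had -0.28 (-0.44 to -0.13). Foxa2 itself (chromosome 2, 148042877 to 148046969) had -0.45 (-0.73 to -0.16), and Nr1h4, which encodes FXR (chromosome 10, 89454234 to 89533645), had -0.31 (-0.49 to -0.12). Cyp8b1, a sterol hydroxylase of bile acid synthesis (chromosome 9, 121914356 to 121916305), had -0.57 (-0.90 to -0.23). Cyp7a1, the rate-limiting enzyme of bile acid synthesis (chromosome 4, 6265612 to 6275632), held 226 and 333 contacts and had 0.05 (-0.20 to 0.30), so no difference was detectable at this depth. Against the median locus at -0.14, the intervals of Abcb11 and Nr1h4 include that value and those of Nr0b2, Slc51b, Foxa2 and Cyp8b1 lie below it. This split depends on the reference: minus the trend with gene density, Cyp8b1 had -0.31 (-0.65 to 0.03), Abcb11 -0.16 (-0.32 to -0.01) and Nr1h4 -0.23 (-0.42 to -0.05). With contacts within a bin, the intervals of Foxa2 (-0.64 to 0.01) and Abcb11 (-0.27 to 0.10) include 0, and Slc51a had -0.45 (-0.87 to -0.04). Among protein-coding loci with at least 200 local contacts, Slc51b lay at percentile 6.32, Nr0b2 at 6.62 and Cyp8b1 at 9.91. Abcb11 lay at 32.7, Slc51a at 38.1 and Cyp7a1 at 78.3.

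**Figure D3:**
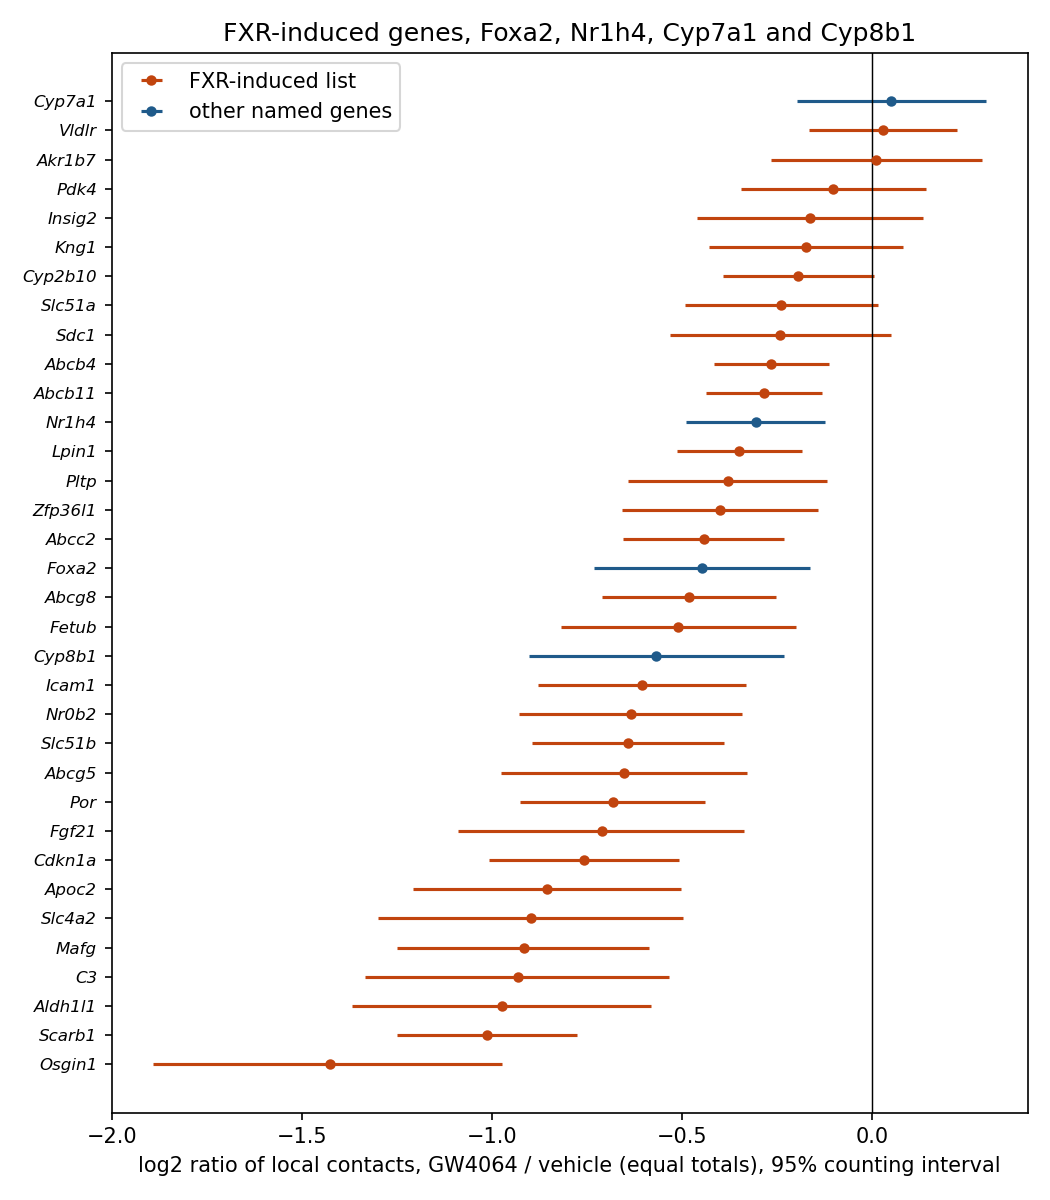
Log2 ratio of local contacts, GW4064 over vehicle after scaling to equal totals, with 95% counting intervals, for the 30 genes of the FXR-induced list and for Foxa2, Nr1h4, Cyp7a1 and Cyp8b1. The values run from Osgin1 at -1.43 to Cyp7a1 at 0.05. Osgin1 is shown as a list member and has under 200 contacts.

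The other lists of bile acid and regulatory genes differed in how far they lay from random loci. For bile acid synthesis and conjugation, 9 of 18 loci were lower and 0 higher, and the median of -0.20 lay at percentile 24.3. Scp2, the sterol carrier of peroxisomes, had -0.77 (interval -0.97 to -0.57), and Cyp39a1, an oxysterol hydroxylase, had 0.16 (-0.03 to 0.34). For bile acid and organic anion transport, 12 of 20 loci were lower and the median of -0.29 lay at percentile 0.19, but at 6.07 with contacts within a bin and at 3.64 without matching. Abcc3, an exporter of the basolateral membrane, had -0.69 (-0.90 to -0.47), and Abcg2, another exporter, had 0.07 (-0.07 to 0.22). Among nuclear receptors of liver, 22 of 30 loci were lower, with a median of -0.31 at percentile 0.03. Rxra, the partner of FXR on DNA, held 360 and 266 contacts and had -0.95 (-1.18 to -0.71), Ppard had -0.87 (-1.10 to -0.65) and Nr2f1 had -0.03 (-0.27 to 0.22). Among Foxa genes and other liver transcription factors, 21 of 26 loci were lower, with a median of -0.35 at percentile 0.01. Creb3l3, a liver factor of lipid metabolism, had -1.06 (-1.42 to -0.71) and Cebpb had -0.76 (-1.08 to -0.44), whereas Zbtb20 had 0.02 (-0.05 to 0.09). Against the median locus, the numbers lower and higher were 4 and 3 for bile acid synthesis, 9 and 2 for transport, 13 and 1 for nuclear receptors, and 15 and 2 for transcription factors.

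Of 5 lists of hepatocyte function, 4 lay in the lowest 2.5% of random lists. For lipid and cholesterol synthesis, 23 of 30 loci were lower and the median of -0.44 lay below all 10000 random lists. Dgat2, which makes triglycerides, had -0.89 (interval -1.22 to -0.56), and Hmgcs1, of cholesterol synthesis, had 0.04 (-0.24 to 0.32). For secreted hepatocyte proteins, 31 of 41 loci were lower, with a median of -0.33 at percentile 0.23. Apoe, whose bins include that of Apoc1, had -0.91 (-1.18 to -0.65) and F9, a clotting factor, had 0.23 with an interval of -0.00 to 0.47. Glucose metabolism had 20 of 27 loci lower and a median of -0.31 at percentile 1.5, with Gcgr, the glucagon receptor, at -0.85 (-1.21 to -0.50) and Gys2, glycogen synthase of liver, at 0.10 (-0.12 to 0.31). Xenobiotic metabolism had 19 of 30 loci lower and a median of -0.35 that lay below all 10000 random lists, with Por, the electron donor of cytochromes P450, at -0.68 (-0.93 to -0.44) and Ahr, the aryl hydrocarbon receptor, at 0.06 (-0.10 to 0.22). Fatty acid oxidation and PPARA targets had 17 of 28 loci lower and a median of -0.32 at percentile 2.52, and lay at 0.55 with total contacts, 1.93 with neighbour bins, 0.55 within 500 kb, 0.79 without matching and 0.03 with genes inside 1 bin. It lay at 3.33 with contacts within a bin, 3.25 with loci of at least 200 contacts, 7.31 matched on gene density and 14.8 matched on density and compartment. Creb3l3 is also on that list, which further holds Lipe, a lipase, at -0.73 (-1.08 to -0.39) and Cd36, a fatty acid transporter, at 0.10 (-0.04 to 0.23). With total contacts in place of local contacts, secreted proteins lay at percentile 12.3, glucose metabolism at 14.5 and xenobiotic metabolism at 16.5. Against random loci of the gene-rich compartment with like gene density, a check added after the data were seen, these 3 lists lay at 6.83, 19.8 and 34.8. Against the median locus, the numbers lower and higher were 19 and 0 for lipid synthesis, 14 and 2 for secreted proteins, 12 and 2 for glucose metabolism, 14 and 3 for xenobiotic metabolism, and 13 and 2 for fatty acid oxidation.

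Immediate early and clock genes lay in the lowest 2.5% of random lists, and acute phase genes did so only under other settings. Immediate early and stress genes had 24 of 31 loci lower and a median of -0.43 at percentile 0.11, with Gadd45b at -1.30 (interval -1.63 to -0.98) and Atf4 at -0.89 (-1.24 to -0.55), and Asns, asparagine synthetase, at 0.08 (-0.18 to 0.35). The circadian clock list had 16 of 22 loci lower and a median of -0.34 at percentile 0.74, with Dbp at -1.10 (-1.50 to -0.70) and Clock at 0.05 (-0.12 to 0.23), and it lay at 5.18 against loci of the gene-rich compartment, at 2.51 with neighbour bins and at 4.25 with genes inside 1 bin. Acute phase and inflammation genes had 15 of 26 loci lower and a median of -0.30 at percentile 5.41, or at 1.36 with contacts within a bin and 1.79 without matching. It lay at 11.4 with total contacts, 13.7 with neighbour bins, 19.7 within 500 kb and 23.4 matched on density and compartment. Its lowest members were Saa2, a serum amyloid gene, at -1.13 (-1.48 to -0.79) and Socs3 at -1.11 (-1.51 to -0.72), and its highest was Tlr4, a receptor of bacterial lipid, at 0.19 (-0.06 to 0.45). Against the median locus, the numbers lower and higher were 18 and 0 for immediate early genes, 9 and 1 for clock genes, and 10 and 3 for acute phase genes.

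The lists of markers of other liver cells and of comparison genes lay within the middle 95% of random lists, though 5 of these 7 lists left it under another setting. Kupffer cell and leukocyte markers had 9 of 22 loci lower and a median of -0.24 (percentile 19.6). Sinusoidal endothelial markers had 10 of 20 lower and a median of -0.23 (percentile 16.3), and lay at 1.41 with total contacts and at 0.11 with contacts within a bin. Stellate cell and fibroblast markers had 6 of 18 lower and 1 higher, with a median of -0.09 (percentile 70.9). Cholangiocyte markers had 7 of 16 lower and 1 higher, with a median of -0.30 (percentile 4.43, or 1.03 with genes inside 1 bin). Skeletal and cardiac muscle genes had 10 of 23 lower and 1 higher, with a median of -0.22 (percentile 28.4, or 0.39 with total contacts). Housekeeping genes had 18 of 30 lower and a median of -0.29 (percentile 4.66). They lay at 1.38 with total contacts, 1.56 with neighbour bins, 1.58 without matching and 0.02 with genes inside 1 bin. Matched on gene density they lay at 25.9, and matched on density and compartment at 72.6. Neuronal genes had a median of 0.01 (percentile 95.9), with 7 of 30 loci higher and 5 lower, and 8 of their loci lay in the gene-rich compartment of the vehicle library. Their percentile was 69.1 after matching on gene density and 98.1 with neighbour bins, and it turned to 0.92 for the 8 loci compared within the gene-rich compartment. Nrg3 of the neuronal list had 0.21 (interval 0.14 to 0.28), and Slc17a7, a glutamate transporter of the same list, had -0.99 (-1.39 to -0.60). Ryr2 of the muscle list had 0.30 (0.19 to 0.41), and Actn3, an actinin of muscle, had -0.60 (-0.89 to -0.31). Minus the trend with gene density, Ryr2 had 0.24 and Actn3 -0.15. The trend also took up part of the low values named above. It left Scarb1 at -0.91, Gadd45b at -0.86, Dbp at -0.66, Creb3l3 at -0.62, Slc17a7 at -0.55, Apoe at -0.47 and Gcgr at -0.41. Dbp and Slc17a7 are near each other on chromosome 7, as are Creb3l3 and Gadd45b on chromosome 10, so these loci are not independent. The members named from the muscle and the other lists are extremes of their lists, so their ratios overstate the difference. With the median locus as the reference, the stellate median becomes 0.05 and the neuronal median 0.15, so the sign of the stellate median depends on the scaling. The numbers lower and higher than the median locus were 6 and 2 for Kupffer, 4 and 0 for endothelial, 4 and 3 for stellate, 5 and 4 for cholangiocyte, 5 and 13 for neuronal, 8 and 2 for muscle, and 13 and 1 for housekeeping genes. In all, 10 of the 20 lists lay in the lowest 2.5% of random lists and 0 in the highest 2.5%, and all 10 also did so against random lists matched on gene density, a check added after the data were seen.

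**Figure D4:**
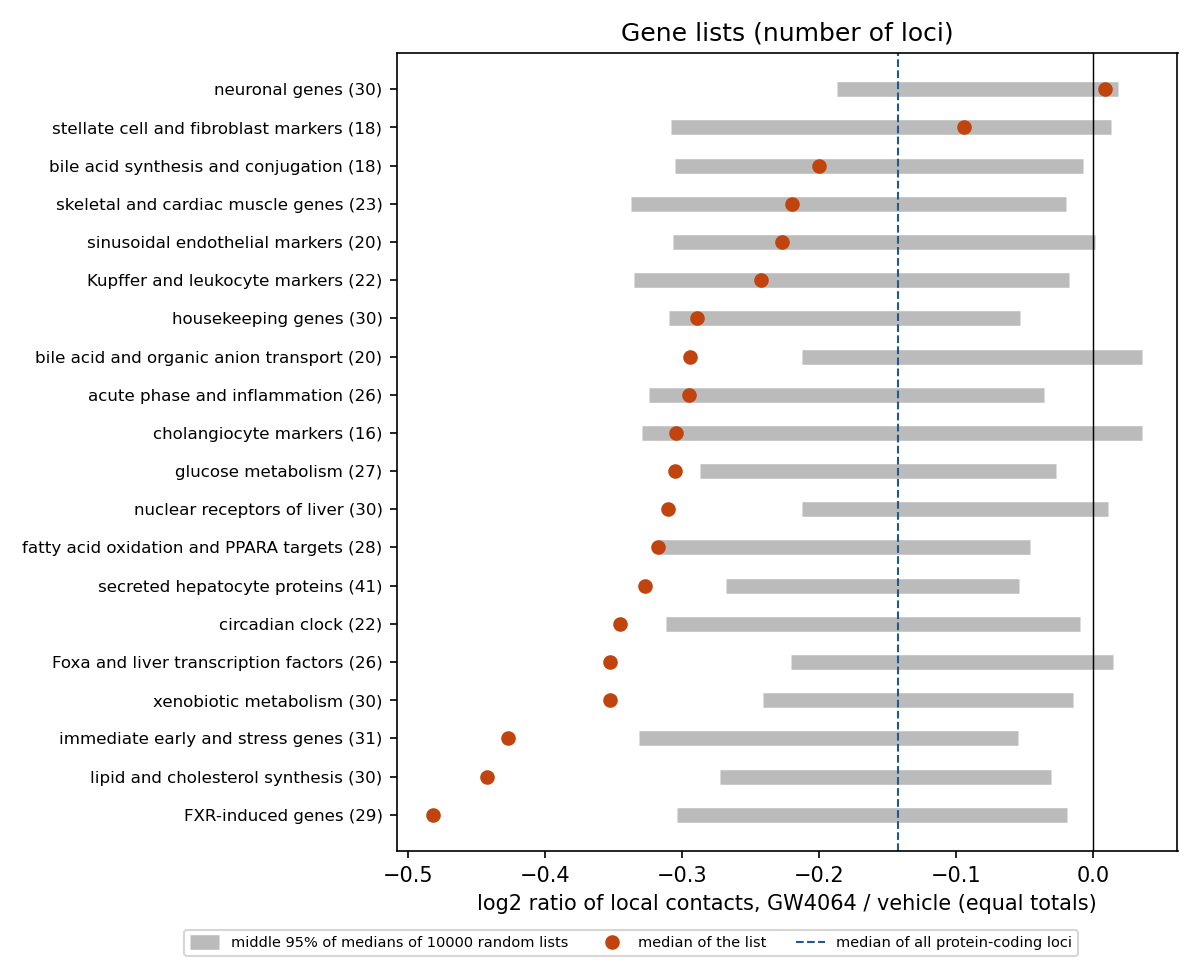
Median log2 ratio of local contacts for each of the 20 gene lists (points), with the middle 95% of the medians of 10000 random lists matched on contacts (grey bars) and the median of all protein-coding loci (dashed line). The FXR-induced list is the lowest, at -0.48, and neuronal genes are the highest, at 0.01.

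The 11 bins with at least 1000 local contacts over both libraries had log2 ratios between -0.24 and 0.17. The bin of Chil4 on chromosome 3 (106200001 to 106250000) had the highest log2 ratio, 0.17 (interval -0.01 to 0.35), next to that of Chil3 at 0.12 (-0.05 to 0.28) in a cluster of chitinase-like genes. The bin with the lowest value, on chromosome 5 from 145600001 to 145650000, had -0.24 (-0.42 to -0.06). Of the 10 bins named by the rule it is the one whose interval excludes 0.

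With distance matching alone, more single bin pairs differed in both directions than in a random split of the pooled contacts. Most of that excess was gone after division by bin coverage. Among 89083 pairs 100 kb to 2 Mb apart with at least 20 contacts, 2011 were at least 2-fold higher in GW4064 and 2211 at least 2-fold lower with intervals excluding 1, against 1350 and 1484 in a random split. After division by the coverage ratios of both bins the numbers were 1503 and 1320, and the random split gave 1384 and 1350. The lower pairs then no longer exceeded the random split. Scaling to equal cis totals instead of totals at the same distance turned the balance, with 3387 higher and 1208 lower, against 1360 and 1321 in a random split. Among pairs with at least 50 contacts, 47 were higher and 111 lower, against 39 and 21 in a random split. Among pairs with at least 50 contacts and a gene, the highest lay at Trpm6, a magnesium channel gene on chromosome 19, between bins starting at 18700001 and 18800001, with 9 vehicle and 46 GW4064 contacts, a ratio of 3.48 (interval 1.68 to 8.09). The pair of Btaf1 and Ide on the same chromosome, 300 kb apart, held 16 and 61 contacts, a ratio of 2.61 (1.49 to 4.85). The lowest lay within Ntrk2 on chromosome 13, with 44 and 21 contacts and a ratio of 0.325 (0.184 to 0.558). The Ugt1a cluster of glucuronosyltransferases on chromosome 1 and the bin of Mroh2a and Hjurp, 150 kb away, held 43 and 22 contacts, a ratio of 0.347 (0.198 to 0.593), and a pair at Hoxc4, Hoxc5 and Hoxc6 held 41 and 21. These pairs were picked as extremes of 4361 pairs, so their ratios overstate the difference, and the ratios were not divided by bin coverage.

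More bin pairs passed the enrichment rule in the GW4064 library. With that library thinned to the cis total of the other, 14652 pairs in vehicle and 18993 in GW4064 held at least 10 contacts and at least 2 times the number expected from distance and coverage, and 6155 were shared, which is 42.0% of the vehicle pairs and 32.4% of the GW4064 pairs. A random split of the pooled contacts into equal parts gave 17151 and 17051 pairs and shared 6757, or 39.4%. In contacts simulated from the distances and coverage of the vehicle library, the rule called 5651 pairs that were not raised. Part of each count can therefore come from counting error. With the libraries thinned to equal contacts at 100 kb to 2 Mb, a setting added after the data were seen, GW4064 had 17371 pairs. Per 100 bins, loci of FXR-induced genes had 77.3 pairs in vehicle and 68.2 in GW4064, and all bins with a protein-coding gene had 68.7 and 87.7. The 44 bins of that list held 34 and 30 pairs, while the share of them with a pair was 50% and 52.3%. Loci of immediate early and stress genes held 59 and 52 pairs, while the share of their bins with a pair was 61.5% and 71.8%. Loci of lipid and cholesterol synthesis genes had 41 pairs in vehicle and 70 in GW4064, and those of xenobiotic metabolism 29 and 47. These counts per list are small, and the pairs expected from counting error were not taken off.

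Few single contacts of the genes chosen in advance differed, and those that did were lower in the GW4064 library, as were the local contacts of their genes. Between 3 and 16 partner bins within 1 Mb of each gene held at least 20 contacts over both libraries. From Slc51b, contacts with the neighbouring bin that holds Pdcd7, Ubap1l, Kbtbd13 and Rasl12 numbered 55 in vehicle and 38 in GW4064, a distance-matched log2 ratio of -1.0 (interval -1.64 to -0.38). From Foxa2, contacts with the bin that starts at 147950001 numbered 59 and 47, or -0.79 (-1.38 to -0.22), the only one of its 5 partners whose interval excludes 0. From Nr1h4, 3 of 8 partners were lower, and contacts with the bin that starts at 89350001 numbered 22 and 13, or -1.32 (-2.43 to -0.26). Its contacts with Uhrf1bp1l numbered 8 and 26, or 1.15 (-0.03 to 2.51), and with scaling to equal cis totals the value was 1.27 with an interval above 0. From Abcb11, 2 of 16 partners were lower, and the bin that starts at 69400001 held 108 and 100 contacts, or -0.67 (-1.07 to -0.26). For Nr0b2, Slc51a, Cyp7a1 and Cyp8b1 every partner's interval includes 0, so no difference was detectable at this depth. The distance-matched ratios were not divided by the change in all local contacts of the gene. Each distance-matched interval below 0 includes the local log2 ratio of its gene. No partner was thus shown to be lower beyond its gene as a whole.

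Compartments kept their positions and were more contrasted in the GW4064 library. The first eigenvectors at 250 kb had a Pearson r of 0.987 across 10135 bins, which are not replicates, against 0.993 between equal random parts of the pooled contacts. The sign differed in 455 bins (4.49%), of which 315 went from the gene-rich to the gene-poor compartment and 140 the other way, and it differed in 291 bins (2.87%) between the random parts. After balancing of the matrices that direction turned, with 161 and 240. No bin changed sign with both values at least 0.5 SD from 0. Compartment strength compares observed over expected contacts over 2 Mb apart within and between the 20% of bins with the highest and the 20% with the lowest eigenvector. It had a median of 6.72 in vehicle and 8.62 in GW4064 and was higher in GW4064 on 20 of 20 chromosomes. The random parts had medians of 7.55 and 7.70. Contacts between these extremes were at 0.266 of the expected number in vehicle and 0.215 in GW4064, those within the gene-poor extreme at 2.41 and 2.80, and those within the gene-rich extreme at 1.25 and 1.02. After balancing, the values were 2.01 and 2.11 within the gene-poor extreme and 1.51 in both libraries within the gene-rich one. Of the 29 FXR-induced loci, 27 lay in the gene-rich compartment in each library and 0 changed sign. Of 20 loci of bile acid and organic anion transport, 16 did so in vehicle and 12 in GW4064, and of 41 loci of secreted hepatocyte proteins 36 and 32. The neuronal list, with 8 and 10 of 30 loci, and the stellate list, with 7 and 9 of 18, went the other way. Nr1h4 went from 0.332 to -0.116 and Cyp7a1 from 0.195 to -0.0625, all small values.

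Most insulation boundaries of the vehicle library had a counterpart in the GW4064 library, and insulation scores at 6 of the 8 genes chosen in advance were lower in GW4064. With a 500 kb window there were 3803 boundaries in vehicle and 3893 in GW4064. Of the vehicle boundaries, 75.7% lay within 1 bin of one in GW4064, against 78.1% between equal random parts of the pooled contacts. Insulation scores had a Pearson r of 0.935 across bins, against 0.981 between those parts. Nr0b2 lay on a boundary in vehicle and 100 kb from one in GW4064, Slc51b 300 kb and 100 kb away, and Foxa2 100 kb away in both. The log2 score went from -0.23 to -0.98 at Nr0b2, from -0.33 to -0.87 at Cyp8b1, from 0.09 to -0.39 at Slc51b, from 0.43 to -0.02 at Slc51a, from 0.17 to -0.28 at Nr1h4 and from 0.01 to -0.34 at Abcb11. At Foxa2 it was 0.03 and 0.07 and at Cyp7a1 -0.39 and -0.23. The score compares raw contacts across a bin with the mean of its chromosome and was not corrected for bin coverage. Fewer local contacts at a gene would also lower it, so these scores do not show a separate change in insulation.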

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

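Of the tests in this part, that of gene density together with compartment for the FXR-induced list and that of compartment contrast had their outcome rules written before the result was seen, and the others, gene density alone included, were chosen only after it was seen. Contacts between the mitochondrial genome and nuclear chromosomes, outside the main measurement and above the 3 counts that 0 allows, numbered 21376 in vehicle and 21044 in GW4064. Contacts within chromosome Y, also outside the comparisons, numbered 17291 and 27904. Both pairs of counts are not scaled for depth. Of all contact ends, chromosome Y held 0.190% in vehicle and 0.192% in GW4064.

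Gene-rich bins held fewer scaled contacts in the GW4064 library. For local contacts, random ligation does not account for it, because contacts between chromosomes, all taken as random, would make up 0.0842% of vehicle local contacts. That test does not cover the gap in contacts between chromosomes. A different fall with distance does not account for the fewer contacts of gene-rich bins either. Contacts within a bin show a log2 gap of -0.34 between gene-rich and gene-poor bins. The gap between compartments was -0.29, which could come from the yield of open chromatin in the immunoprecipitation, from base composition or from the treatment. With 1 library per group and no base composition used, these cannot be told apart.

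Of the 10 liver lists, 8 lay below random gene loci, all but bile acid synthesis and fatty acid oxidation. Gene density alone does not account for the FXR-induced list, whose median lay -0.30 from that of random lists matched on it. Against random loci that were also positive in both libraries, the list lay -0.23 away, at percentile 0, which its rule had set against density together with compartment. That match used the sign of the eigenvector and not its size, so it cannot exclude a part of the position within the compartment. The secreted hepatocyte, glucose, xenobiotic and clock lists were the low lists that were no longer low with matching on density and compartment. The lowest percentile of these 4 lists was then 5.18. They were picked by that outcome, so it is no separate test, and density together with compartment could account for their low values. For the FXR-induced list, treatment and a library difference at active liver loci both stay open, untested.

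The GW4064 library had fewer contacts between chromosomes and a stronger compartment contrast. The share of mitochondrial contacts that join nuclear chromosomes went from 40.8% to 29.5%, a difference of -11.3 percentage points, which is consistent with less random ligation as a source of the fewer contacts between chromosomes. Random ligation does not account for the compartment contrast, because the median strengths still differed by 2.08 after the rate of contacts between chromosomes was taken off. Whether treatment or another library difference lies behind the contrast stays open, as the design gives 1 library per group.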

How the results depend on the processing

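The settings with genes inside 1 bin, with matching on gene density or compartment, with thinning to contacts at 100 kb to 2 Mb and with compartments corrected for contacts between chromosomes were chosen after seeing the data. Of 274 alternative values, 209 kept their direction and side of the threshold or moved little, and 1 reversed. Of the 209, 150 are list percentiles that stayed on their side of the threshold. Moves such as from 3803 to 5361 vehicle boundaries with a 250 kb window were counted as little. Some values could not change, such as the 14652 vehicle pairs when thinning of the other library was left out. The tally is therefore no measure of robustness. Of 10 low lists, 5 were low under all 9 list alternatives: FXR-induced genes, nuclear receptors, Foxa and liver transcription factors, lipid and cholesterol synthesis, and immediate early and stress genes. The start-site bin was not run, since the gene table gives no strand. Depth limits single bin pairs, as most pairs hold 1 contact. Except where fewer bins or pairs were tested, the cause was not tested.

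On autosomes only, the difference in percentage points was 2.04 within a bin and -3.89 between chromosomes. With contacts within a bin left out, it was 2.30 at 100 kb to 500 kb and -4.64 between chromosomes. The slope difference from 500 kb to 5 Mb was -0.0585. Bin coverage gave 48 higher bins with no minimum, 326 lower with a minimum of 1000, and 5 higher and 23 lower at 2-fold. Local contacts gave 167 higher with no minimum, 0 higher and 0 lower with a minimum of 1000, which 11 bins reach, and 3 higher and 89 lower at 2-fold.

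With total contacts the percentiles were 12.3 for secreted proteins, 14.5 for glucose, 16.5 for xenobiotic metabolism, 0.55 for fatty acid oxidation, 1.41 for endothelial, 0.39 for muscle and 1.38 for housekeeping genes. With contacts within a bin they were 6.07 for transport, 15.8 for xenobiotic metabolism, 1.36 for acute phase and 0.11 for endothelial genes. With neighbour bins they were 1.93 for fatty acid oxidation, 2.51 for clock, 98.1 for neuronal and 1.56 for housekeeping genes. Within 500 kb, fatty acid oxidation lay at 0.55. Without matching, they were 3.64 for transport, 0.79 for fatty acid oxidation, 1.79 for acute phase, 99.4 for neuronal and 1.58 for housekeeping genes. With genes inside 1 bin they were 0.03 for fatty acid oxidation, 4.25 for clock, 1.03 for cholangiocyte and 0.02 for housekeeping genes. Matched on gene density and compartment they were 6.83 for secreted proteins, 19.8 for glucose, 34.8 for xenobiotic metabolism and 5.18 for clock, and neuronal genes reversed to 0.92, on 8 loci.

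Bin pairs gave 4851 higher and 5262 lower with a minimum of 10, 47 and 111 with a minimum of 50, and 3387 and 1208 with equal cis totals, where random splits gave 3351 and 4198, 39 and 21, and 1360 and 1321. Divided by bin coverage, 1320 were lower. Enriched pairs numbered 4698 in vehicle and 7047 in GW4064 with 1780 shared at 3 times expected, and 2672 and 3292 with 1314 shared at 20 contacts. From distance alone, 25245 were in vehicle and 10910 shared. With no thinning GW4064 had 29020, and 11123 were shared within 1 bin. The compartment sign differed in 182 bins at 500 kb and in 0 with both values at least 0.5 SD from 0. With equal cis totals the highest Nr1h4 partner was at 1.27, with an interval that then excludes 0.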

Other observations

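In this part, the regions, and the set of liver lists with which FXR-induced loci were compared, were chosen only after their values were seen, as was the test that allows for the choice of the lowest list, while the outcome rules of the other tests on those lists were written before those tests were run. The immunoglobulin heavy chain variable region on chromosome 12, 44 bins with 159 Ighv segments, held 3782 vehicle and 7907 GW4064 local contacts, a log2 ratio of 0.55 (interval 0.50 to 0.61), and 44 of its 44 bins lay above 0. A stretch of 23 bins on chromosome 17 without protein-coding genes, around the bin from 92300001 to 92350000, held 2886 and 6026, also 0.55 (0.49 to 0.62). With contacts within a bin the regions on chromosomes 12 and 17 had 0.66 and 0.52, and with total contacts 0.50 and 0.42. The difference was thus not particular to local contacts. Neighbouring bins share local contacts, so the bins of a region are not independent. The part of the histone gene cluster on chromosome 13 that holds H4c11 and H1f5 and the part that holds H1f3 and Hfe, whose near-identical genes leave the placement of reads uncertain, contacted each other 244 times in vehicle, 10.2 times the number expected (8.99 to 11.6), and 325 times in GW4064, 12.6 times (11.3 to 14.1).

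The FXR-induced list had the lowest median of the 10 liver lists, and a hypothesis was that contacts at loci FXR induces were lower beyond those of other liver loci. Its median of -0.48 lay at percentile 0.32 of random lists drawn from the 233 loci of the other 9 liver lists, whose median was -0.32, and at 1.02 with matching on gene density. The list was singled out as the lowest of the 10, which these percentiles leave out of account. When all 10 lists were drawn at random from their joint loci, the lowest of them was as low in 11.4% of draws, and in 17.1% with matching on gene density. The percentiles of 0.32 and 1.02 both lie in the lowest 2.5%, where a list is called low. The draws that count the choice, a test added after the values were seen, do not set the list apart. Because these tests differ in outcome, the hypothesis stays undecided, and neither it nor gene density is excluded.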
